A study of Mus musculus with 4 samples.

How the data were processed

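Gene expression was measured by RNA sequencing in primary mouse embryonic fibroblasts (MEFs), cells grown out from mouse embryos and used before they become an established line. All 4 cultures had received 100 nM SAG, a small-molecule agonist of Smoothened that switches on Hedgehog signalling, for 24 h. The 4 libraries were wild type, Dyrk2 knockout, wild type with a negative-control siRNA (siNeg) and wild type with an siRNA against Dyrk2 (siDyrk2). Each group held 1 library, and the labels do not say whether the cultures came from separate embryos. Cultures without SAG were not analysed here.

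Per the labels' protocols, total RNA was extracted on columns with DNase treatment and made into stranded libraries after polyA selection. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1 and the GRCm38 mouse genome, without their order or settings. The counting program and the gene annotation are not given in the sources used here. The deposited values are FPKM, fragments per kilobase of exon and per 1e+06 fragments, per the file headers, which also give the authors' exonic length of each gene. In each file FPKM multiplied by length in kilobases summed to 1e+06 within rounding, so the deposited FPKM values were scaled by the fragments assigned to genes. Values carry 2 decimals. Each file held 55573 gene identifiers, of which 55394 matched GENCODE M21 on GRCm38. Symbols, gene types and coordinates came from that annotation, and the other 179 identifiers were kept without a symbol.

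The files give no read counts, but FPKM moves in steps of 1 fragment for a given length and depth. The depth that made the values of genes no longer than 200 bases whole was searched for in each library. It placed 100% of 324 to 386 such genes on a whole number of fragments within the rounding of the deposited values. The estimates were 23.9 M fragments (M, 1e+06) for wild type, 21.9 M for the knockout, 20 M for siNeg and 21.5 M for siDyrk2. A floor of 3 fragments for a gene of 2 kb corresponded to 0.0627, 0.0686, 0.0751 and 0.0699 FPKM in the same order. Counting intervals are exact 95% conditional binomial (Clopper-Pearson) intervals on these estimated fragments. They cover counting error only and not differences between cultures.

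The plan had assumed count tables. Because the files hold FPKM, the fallback written into the plan was used: the same rules on the deposited FPKM, with limma on a log2 scale for the joint fit. Count models were not run. The plan had named trimmed-mean scaling as the main one. After the values were seen the deposited scaling was used instead, since it already equals scaling to total fragments, and trimmed-mean scaling became an alternative. The G2/M list was taken up as a lead result after its value was seen. Ratios are log2((FPKM + 1)/(FPKM + 1)), which understates differences of genes with low values. Ratios written as "fold" are ratios of the deposited FPKM without the pseudocount. Genes counted as at least 2-fold different are so on FPKM + 1.

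The comparisons were knockout against wild type and siDyrk2 against siNeg, with siNeg against wild type as a comparison of both controls. With 1 library per group no test was made within a comparison. Genes were counted by a fixed rule of size: at least 2-fold different on the log2(FPKM + 1) scale among 12817 genes with at least 1 FPKM in 1 or more of the 4 libraries. For each of 43 gene lists fixed before the data were examined, the median log2 ratio was placed among 10000 random lists of the same size, matched on deciles of mean expression. Percentiles were given for lists with at least 3 measured members and describe these libraries only. The intervals drawn for list medians are 95% order-statistic intervals over genes.

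A joint fit asked which genes differed in both comparisons. It used limma 3.58.1 in R 4.3.3, with moderated variances and a mean-variance trend, an option the plan had not fixed, on log2(FPKM + 1) of 12219 genes with at least 1 FPKM in 2 or more libraries. Its terms were the approach (knockout pair or siRNA pair) and lowered Dyrk2, which left 1 residual degree of freedom. P-values were adjusted by Benjamini-Hochberg over all genes, and for each list also over the list alone. They measure only the disagreement between both ways of lowering Dyrk2 in these 4 libraries.

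The genes to be named were set by rule before the data were examined, and not every gene the rule selected is named in the text. For each comparison they were Dyrk2, the measured Hedgehog targets and co-receptors, and the 8 highest and 8 lowest genes among those with a symbol and at least 5 FPKM in the higher library. Gene models named Gm plus digits, Rik names and -ps pseudogenes were left out. Up to 4 members of every other list followed, by size of ratio. For both comparisons together the rule took the 10 higher and 10 lower genes with the largest smaller ratio, and the 10 smallest p of the joint fit.

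The joint fit was tested on simulated libraries of the same depth and 12219 genes, with 100 genes made 4-fold lower, 100 made 2-fold lower and 12019 unchanged. The first simulation gave every gene the same spread. The fit called 100 of the 4-fold and 99 of the 2-fold genes, and also 94 unchanged ones, so 94 of 293 calls at an adjusted p under 0.05 were false. The simulation was then changed, after that result, to a spread that varied between genes, closer to the prior degrees of freedom of the real fit (3.3). In the second simulation the fit called 0 of the 4-fold, 0 of the 2-fold and 0 of the unchanged genes. At an unadjusted p under 0.05 it found 99% and 90% of the lowered genes and 4.80% of the unchanged ones, against 100%, 100% and 5.78% in the first. Robust variance moderation was also tried on the simulated data, did not alter the calls, and was not used. The adjusted p of the joint fit thus depend on a spread that 4 libraries cannot fix. In the simulated knockout comparison the rule of size found 97% of the 4-fold genes in both simulations, 31% and 33% of the 2-fold genes, and 0.141% and 1.31% of the unchanged ones. With the varied spread a simulated list of 20 genes made 4-fold lower fell at percentile 0, and 4.5% of 200 unchanged lists lay outside percentiles 2.5 to 97.5. The simulated genes varied independently, so this share does not cover real lists whose genes move together between libraries. A word planted in 3' untranslated regions ranked 1.

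Alternatives were trimmed-mean and median-of-ratios scaling, pseudocounts of 0.25 and 5 FPKM, no filter or a filter of 10 FPKM, a 1.5-fold rule, protein-coding genes only, a core Hedgehog list, other terms in the joint fit and leaving out each library. Exchanged controls, the removal of genes with 2 short sequence words and pseudocounts in the joint fit were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the remaining computation. Genes with near-identical copies, such as ferritin, histone, Hspa1 and ribosomal protein genes, are uncertain, because the treatment of multiply mapped fragments is not given in the sources used here.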

Results

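The series was made to study how the kinase DYRK2 regulates Hedgehog signalling. The data are 4 RNA sequencing libraries of SAG-treated primary mouse embryonic fibroblasts, 1 per group: wild type, Dyrk2 knockout, siNeg and siDyrk2. Estimated depth was 23.9, 21.9, 20 and 21.5 M fragments (M, 1e+06) in that order, and 11939 to 12106 genes reached 1 FPKM in each library. Because no group had a replicate, each difference below is between libraries and has no replicate check.

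Dyrk2 itself was low in both libraries where the labels say it should be. The gene (ENSMUSG00000028630) lies on chromosome 10 at 118855603 to 118870209 (GRCm38) and encodes a dual-specificity kinase. Its level was 6.59 FPKM in wild type and 0.57 in the knockout, an 11.6-fold lower value (95% counting interval 9.17 to 14.7). It was 7.06 FPKM with siNeg and 0.81 with siDyrk2, an 8.72-fold lower value (7.12 to 10.7). The gene-level values do not show which exons the remaining fragments came from.

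The knockout comparison asked what loss of Dyrk2 did to SAG-treated fibroblasts. The Hedgehog feedback genes were far lower in the knockout. Gli1, the pathway's transcriptional effector, was at 28.81 FPKM in wild type and 0.24 in the knockout, a 120-fold lower value (82.5 to 186). The receptor gene Ptch1 was 13.3-fold lower (11.9 to 14.7), and Hhip, which encodes a membrane antagonist of Hedgehog ligands, 25.8-fold lower (17.8 to 38.2). Gli2, the main activator upstream of Gli1, was also lower, at 8.66 against 20.38 FPKM.

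Of 22 Hedgehog target genes, 15 were measured and 11 of them were lower in the knockout, 4 by at least 2-fold. The list's median log2 ratio was -0.55 (95% order-statistic interval over genes -1.84 to 0.15), at percentile 0 of the random lists. Foxd1 (-0.78) and Foxc2 (-0.55), forkhead transcription factors, the survival gene Bcl2 (-0.78) and cyclin D1 (Ccnd1, -0.74) were lower by smaller amounts. Ccnd2 (-0.18), Rab34 (-0.30) and Jag1 (-0.26) differed little, and Igfbp6 (0.54), Osr1 (0.39), Sfrp1 (0.38) and Nrp2 (0.15) were higher. The co-receptor genes that Hedgehog signalling represses were all higher, with Gas1 at 0.74, Cdon at 0.22 and Boc at 0.21. Gli1 lies on chromosome 10 at 127329882 to 127341974, Ptch1 on chromosome 13 at 63508328 to 63573598, Hhip on chromosome 8 at 79965851 to 80058006 and Gli2 on chromosome 1 at 118834132 to 119053619.

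**Figure D1:**
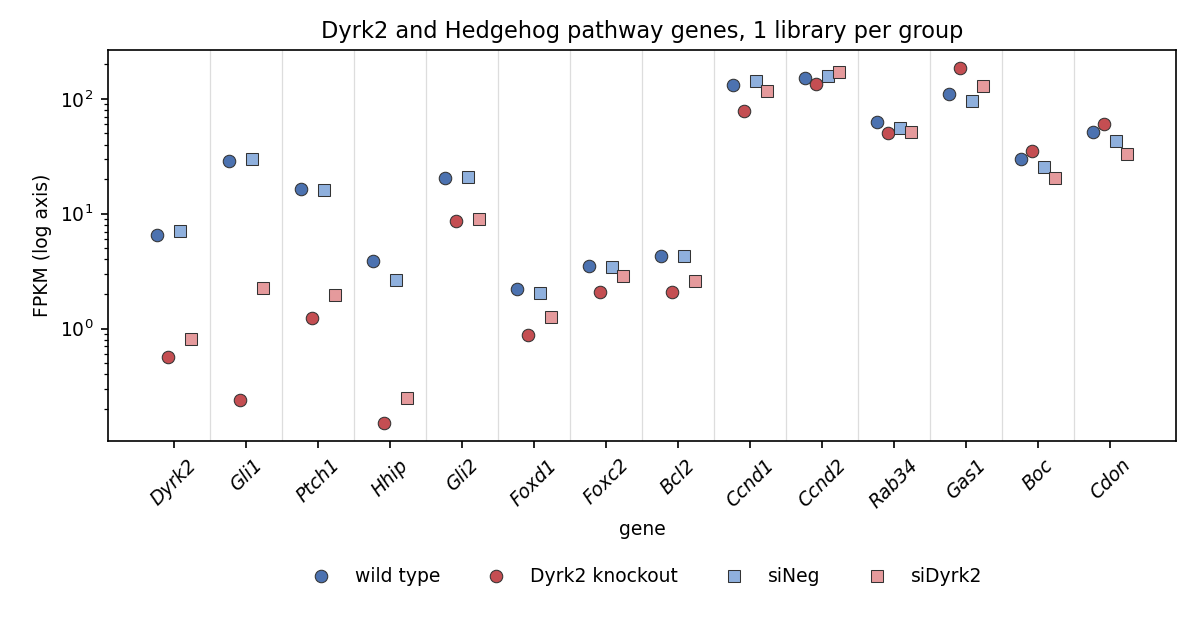
FPKM (log axis) of Dyrk2, Hedgehog targets and pathway genes in the 4 libraries, 1 point per library, circles for the knockout pair and squares for the siRNA pair. Gli1 was at 28.81 and 30.17 FPKM in the controls, and at 0.24 in the knockout and 2.25 with siDyrk2.

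Most other pathway, intraflagellar transport and transition zone genes were close to wild type. The 30 measured pathway components had a median of -0.04, and only Gli2 (-1.15) was at least 2-fold different among them. Tulp3, a ciliary trafficking factor, was at -0.40, Disp1, which releases the ligand, at 0.48 and the kinase gene Ulk3 at -0.20. The 37 measured intraflagellar transport and BBSome genes had a median of -0.01 and the 26 transition zone and basal body genes of -0.00. Of 7 measured cilium disassembly factors 2 were at least 2-fold lower, Plk1 (-1.52) and Aurka (-1.10), both also on the G2/M list. The 5 measured related DYRK and HIPK kinases had a median of 0.02, and 4 genes of the EDVP ubiquitin ligase list, whose scaffold is DYRK2, had -0.13. The 18 measured neighbours of Dyrk2 had a median of -0.07.

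Genes for cell division formed the largest other group that was lower in the knockout. All 24 measured G2/M genes were lower, 19 of them by at least 2-fold, with a median of -1.11 (percentile 0). They included the mitotic kinases Plk1 (-1.52) and Aurkb (-1.38), the DNA topoisomerase Top2a (-1.42) and the proliferation marker Mki67 (-1.37). All 26 G1/S genes were lower too, with a median of -0.72 (percentile 0), among them Uhrf1 (-1.54), Ccne2 (-1.44), Rrm2 (-1.26) and Mcm5 (-1.20). All 26 cholesterol and lipid synthesis genes were lower, with a median of -0.55 (percentile 0), such as Fdps (-0.79), Acat2 (-0.75) and Fdft1 (-0.70). In the comparison of both controls the G2/M median was 0.48, higher with siNeg than in wild type.

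Markers of some other cell types were higher in the knockout. All 11 measured macrophage and leukocyte markers were higher in the knockout, with a median of 0.81 (percentile 100), including the lysozyme gene Lyz2 (329 against 152 FPKM), Ctss (1.11), Fcer1g (0.91) and Tyrobp (0.84). Of 9 adipocyte markers 4 were measured, and all 4 were higher, with a median of 0.50, led by the fatty acid receptor gene Cd36 (1.13). Of 21 measured interferon-stimulated genes 19 were higher, with a median of 0.40 (percentile 100). Macrophage markers and interferon-stimulated genes were also higher with siNeg than in wild type, in 11 of 11 and 16 of 21 genes, with medians of 0.43 and 0.20. Wild type was thus the lower library for these lists in a comparison with intact Dyrk2 as well. The Y-linked genes Ddx3y, Eif2s3y and Uty were at 8.28, 4.58 and 1.12 FPKM in the knockout and at 0.02 FPKM or less in the other 3 libraries. Against a floor of 3 fragments Eif2s3y was at least 152-fold and Uty at least 87.5-fold higher than in wild type. In the same libraries Xist, transcribed from the inactive X chromosome, was at 26.37 FPKM in the knockout, 37.05 in wild type, 32.33 with siNeg and 27.48 with siDyrk2.

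By the rule of size 73 genes were higher and 155 lower in the knockout, of 12817. With protein-coding genes alone the counts were 27 and 85 of 11128, and 99 of the 116 other genes held at most 20 fragments in every library. These 116 included 43 microRNA precursors, 25 small nucleolar RNAs and 27 processed pseudogenes. Among genes with at least 5 FPKM in the higher library, the highest named after Ddx3y were Clec3b (tetranectin, 4.41-fold, 3.99 to 4.88), Angptl4, an inhibitor of lipoprotein lipase (3.41-fold, 3.06 to 3.80), and Sfrp2, a secreted Wnt modulator (3.30-fold, 3.19 to 3.42). Olfm2 (1.32), the interferon-induced Ifit3 (1.27) and Ifit1 (1.27) and the alcohol dehydrogenase Adh1 (1.24) followed. Ddx3y was 414-fold higher, with a counting interval of 142 to 4260.5 because wild type held 2 fragments. Among the lowest besides the Hedgehog genes and Dyrk2 were the crosslinking enzyme gene Tgm2 (-2.45), the leptin receptor Lepr (-2.27), the microRNA precursor Mir483 (-1.91, 13 against 2 fragments) and the polysialyltransferase gene St8sia2 (-1.59).

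The other lists of at least 10 measured members moved less or in mixed directions. Matrix genes had a median of 0.07 over 33 members, with Dcn (0.98), Lum (0.87) and Ogn (0.62), small leucine-rich proteoglycans, the highest. The contractile, SRF and YAP list had a median of -0.24 (15 of 19 lower), with the smooth muscle genes Cnn1 (-1.05), Actg2 (-0.88) and Acta2 (-0.73) lower. NRF2 targets had a median of 0.24 (15 of 17 higher) and NF-kB genes of 0.26 (13 of 17 higher), each at percentile 100. Immediate early genes had 0.20 (13 of 15 higher), proteasome subunits -0.13 (30 of 31 lower) and endoplasmic reticulum chaperones -0.13 (10 of 11 lower).

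The siRNA comparison asked what a short-term lowering of Dyrk2 did in wild-type cells. The same Hedgehog genes led. Gli1 was at 30.17 FPKM with siNeg and 2.25 with siDyrk2, a 13.4-fold lower value (11.8 to 15.4). Ptch1 was 8.22-fold lower (7.54 to 8.97) and Hhip 10.6-fold (7.82 to 14.4). Gli2 was at 9.05 against 20.80 FPKM, a log2 ratio of -1.12.

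Of the 15 measured Hedgehog targets 12 were lower with siDyrk2, 4 of them by at least 2-fold, and the median was -0.23 (-1.54 to -0.08, percentile 0.03). Bcl2 (-0.56), Foxd1 (-0.43), Ccnd1 (-0.27) and Foxc2 (-0.21) were lower, and Jag1 (0.45), Ccnd2 (0.10) and Osr1 (0.08) were higher. Gas1 was higher (0.42), while Cdon (-0.36) and Boc (-0.30) were lower, unlike in the knockout. Among the 30 pathway components, with a median of -0.05, Gli2 alone passed 2-fold, and Prkacb, a catalytic subunit of protein kinase A, was at 5.62 against 10.72 FPKM (-0.82). Tulp3 was at -0.38. The intraflagellar transport list had a median of 0.09, the transition zone list of 0.00, the DYRK and HIPK kinases of -0.04, the EDVP list of -0.12 and the neighbours of Dyrk2 of 0.09.

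Cell division genes differed less with siDyrk2. The G2/M median was -0.09 (0 of 24 at least 2-fold different), with Plk1 at -0.24 and Mki67 at -0.27. The G1/S median was -0.21 (percentile 0, 23 of 26 lower), with Ccne2 at -0.85. The cholesterol list had 0.02. Macrophage markers were higher in 11 of 11, with a median of 0.26 (percentile 99.6), and interferon-stimulated genes had 0.26 (17 of 21 higher), including Isg15 (0.80). The contractile list was higher, with a median of 0.43 (16 of 19 higher, percentile 100), with Acta2 at 0.85 and Actg2 at 39.04 against 19.03 FPKM. The difference between both comparisons in these lists was not tested.

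By the rule of size 96 genes were higher and 102 lower with siDyrk2, and 38 and 48 among protein-coding genes. Among genes with at least 5 FPKM in the higher library, the highest named after the small nucleolar RNA Snord73a were Kif1a, a motor of axonal transport (4.57-fold, 4.21 to 4.95), Rgs4, a regulator of G-protein signalling (4.52-fold, 3.67 to 5.60), and the homeobox gene Meox1 (3.27-fold, 2.91 to 3.67). Map3k7cl (1.57), the histone gene Hist1h2bc (1.53), Reg1 (1.52) and the ferritin heavy chain Fth1 (1.49) followed. Snord73a was at least 3.41-fold higher, with 11 fragments against 0. Kif1a, Hist1h2bc and Fth1 were lower in siNeg than in wild type, at -1.77, -1.56 and -1.04. Among the lowest besides the Hedgehog genes and Dyrk2 were Tgm2 (-2.10), the imprinted zinc finger gene Zim1 (-2.07), St8sia2 (-1.83) and Ssr1, part of the translocon-associated complex (-1.79).

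Other lists in the siRNA comparison had small medians. Cytosolic ribosomal protein genes were at 0.17 (77 of 89 higher, percentile 100), mitochondrially encoded genes at 0.22 (19 of 21 higher) and immediate early genes at 0.30 (14 of 15 higher), a list that was lower in siNeg than in wild type by more (-0.52). Matrix genes were at 0.07, with the adhesion-modulating glycoproteins Tnc (153.89 against 71.41 FPKM) and Thbs1 (0.74) higher and Sparc (-0.78) lower. Hypoxia and glycolysis genes were at 0.15, NF-kB genes at 0.16 and proteasome subunits at 0.07. NRF2 targets (-0.01) and chaperones of the endoplasmic reticulum (-0.01) were near 0.

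Both comparisons were then set side by side, since they used separate control libraries. Lower genes were shared far more often than independent lists would give: 31 genes were at least 2-fold lower in both, against 1.23 for independent lists, and 2 were higher in both, against 0.547. Among protein-coding genes 22 were lower in both, against 0.367 for independent lists, 1 was higher in both and 0 went in opposite directions. With all genes 16 went in opposite directions, against 1.74 for independent lists. With a pseudocount of 5 FPKM 0 genes did so, and with a filter of 10 FPKM 1 did. This excess thus lay outside protein-coding genes and depended on the treatment of low values. The all-gene count of 31 includes such genes too, so its distance from 1.23 is less certain than the protein-coding counts. Gli1, Ptch1, Dyrk2, Tgm2 and St8sia2 were among the lowest in both, as were Tspan11 (9.29 against 28.06 and 7.12 against 23.74 FPKM), the angiopoietin gene Angpt4 (-1.38 and -1.37), the serpin Serpinb9b (-1.35 and -1.33) and Zim1 (-1.31 and -2.07).

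Of the genes named as higher in both, Ccl2 alone passed the rule of size on FPKM + 1 in each comparison, and the others fell short in 1 or both. Without the pseudocount others could pass, such as Ifit1, at 7.42 against 2.49 and 7.21 against 3.37 FPKM. The chemokine genes Ccl2 (1.01 and 1.23) and Ccl7 (0.89 and 0.93), the tissue factor gene F3 (0.93 and 1.14), Ifit1 (1.27 and 0.91), Chchd10 (1.15 and 0.89) and Meox1 (0.86 and 1.60) led. Pgm5 (0.87 and 0.86), the metallothionein Mt2 (0.86 and 1.39), Slfn5 (1.01 and 0.85) and Pamr1 (0.80 and 0.78) completed the 10 genes of the rule. For Ccl2, Mt2 and Pamr1 the siRNA ratio came with a low siNeg value: with siDyrk2 they were at 28.40, 45.54 and 16.87 FPKM, and in wild type at 28.76, 50.61 and 17.41. Across the 12817 genes the log2 ratios of both comparisons had a Pearson correlation of 0.243 and a Spearman correlation of 0.221, as a description, since genes are not replicates. Without the Hedgehog targets and Dyrk2 the Pearson value was 0.222.

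**Figure D2:**
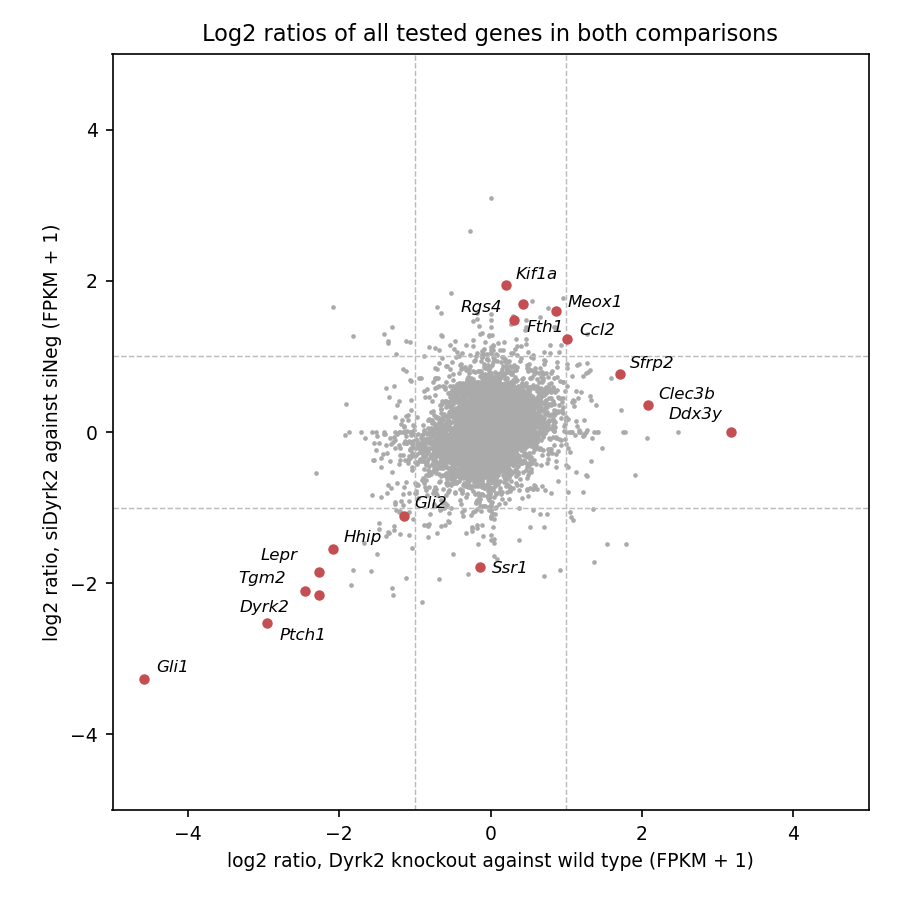
Log2 ratio of each of 12817 genes in the knockout comparison (x axis) and the siRNA comparison (y axis), on FPKM + 1, with dashed lines at 2-fold and named genes in red. Gli1 (-4.59 and -3.26), Ptch1 (-2.96 and -2.53) and Tgm2 (-2.45 and -2.10) lie farthest toward the lower left, and Clec3b (2.09 and 0.36) and Ssr1 (-0.14 and -1.79) lie near 1 axis.

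The joint fit with limma called 0 of 12219 genes at an adjusted p under 0.05, and 1060 had an unadjusted p under 0.05 against 611 by chance. Without the approach term 597 genes had an unadjusted p under 0.05 by limma, so the excess over chance depended on that term. In the main fit the smallest adjusted p from limma was 0.142, and Ptch1, Dyrk2, Tgm2, Tspan11 and St8sia2 were among the genes at that value. Lepr, Angpt4 and Trabd2b were also among the 10 smallest. Adjusted over the list alone, 6 of the 15 Hedgehog targets were lower, among them Gli1, Ptch1, Hhip, Foxd1 and Bcl2. Adjusted over the list alone, Gli2 was lower among 29 pathway components, Gas1 was higher among 3 co-receptors, and 6 of 11 macrophage and leukocyte markers were higher. No adjustment was made across lists, and members of a list that move together in the same libraries are not separate evidence. On simulated data the number of calls depended on the spread assumed: 293 genes with an equal spread, 94 of them false, and 0 with a spread that varied between genes.

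The comparison of both controls, siNeg against wild type, gave 119 genes at least 2-fold different, 47 higher and 72 lower, and 17 of them were protein-coding. Gli1 (0.06) and Ptch1 (-0.02) were nearly equal in both controls. Immediate early genes were lower with siNeg in 15 of 15, with a median of -0.52 (percentile 0). Macrophage markers were higher in 11 of 11, with a median of 0.43 (percentile 100), and G2/M genes in 24 of 24 (percentile 100). Interferon-stimulated genes were higher in 16 of 21, with a median of 0.20 (percentile 99.99). Percentiles at or near 0 and 100 thus also occurred between libraries with intact Dyrk2, and alone do not tie a list to Dyrk2.

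**Figure D3:**
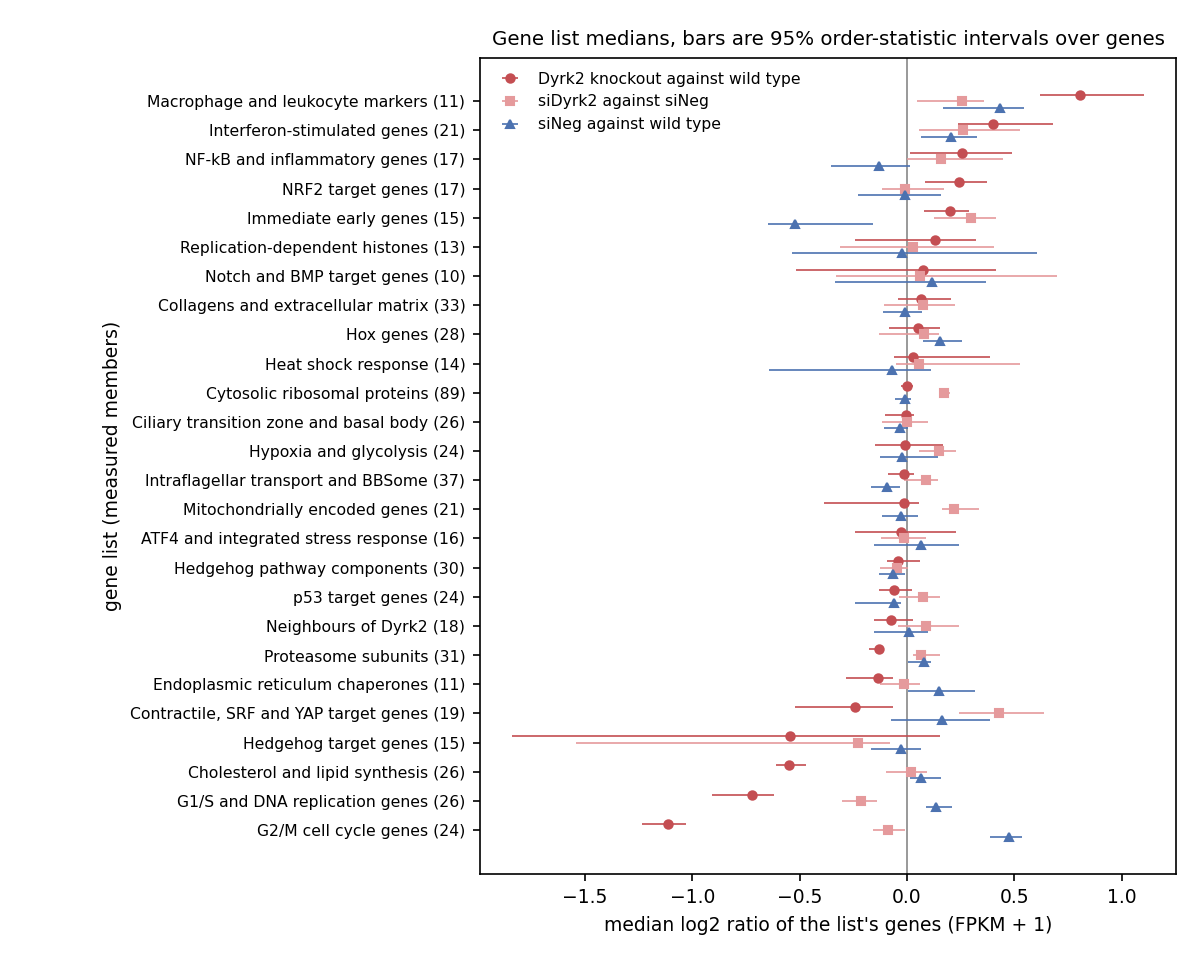
Median log2 ratio of the 26 gene lists with at least 10 measured members in the knockout comparison (circles), the siRNA comparison (squares) and the comparison of both controls (triangles), with 95% order-statistic intervals over genes. The G2/M list lies at -1.11, -0.09 and 0.48 in these comparisons.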

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

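The tests of the cell division and Y-linked patterns, the test of the siNeg library and the test of an siNeg sequence word were chosen after their results had been seen. The tests of an siDyrk2 word and of a GC or length trend were written down before their results were seen. The siRNA pattern was narrowed to protein-coding genes before its tests were run.

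Contractile genes went in opposite directions in the knockout and siRNA comparisons, and this difference was not tested, since each rests on 1 library per group. Acta2, smooth muscle actin, was at -0.73 in the knockout and 0.85 with siDyrk2, a difference of -1.58, and Actg2 at 11.75 against 22.47 FPKM and 39.04 against 19.03 FPKM, a difference of -1.88. The contractile, SRF and YAP list had medians of -0.24 and 0.43, a difference of -0.67. Pericyte and smooth muscle markers had -0.26 and 0.29, a difference of -0.55. Their median was -0.41 in siNeg against wild type, so the 0.29 rests in part on a low siNeg value.

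G2/M genes were lower in the knockout by more than with siDyrk2, and this difference was not tested. Dilution by other cell types would lower fibroblast matrix genes as well, but their median was 0.065 (-0.044 to 0.21). With acute lowering of Dyrk2 messenger RNA by siDyrk2 the G2/M median was -0.089 (-0.16 to -0.01), short of the size seen in the knockout. That value is part of the pattern itself and rests on 1 library and its control, so it is no separate test of acute lowering. For G1/S genes acute lowering stays open as a part of the difference, since 23 of 26 were lower with siDyrk2. Their median was -0.21 (-0.30 to -0.14) against -0.72 (-0.91 to -0.62) in the knockout. Part of the -0.21 may lie in the siNeg control, where 25 of 26 G1/S genes were higher than in wild type, with a median of 0.13. A different embryo or culture state of the knockout cells cannot be told apart from the genotype, because the knockout genotype had 1 library. The intact controls themselves differed by 0.48 in the G2/M list. Both lay above the knockout, whose G2/M median was -1.11 against wild type and -1.55 against siNeg. A slower effect of lasting Dyrk2 loss stays open and was not tested.

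Y-linked transcripts were present in the knockout library alone. All 4 Y-linked genes examined, Ddx3y, Eif2s3y, Uty and Kdm5d, were above 3 estimated fragments there and at 2 or fewer in the other libraries, so male cells in the knockout culture are a candidate explanation. Xist at 26.37 FPKM in the same library is consistent with a mixture of male and female cells, but Xist was at 27.48 FPKM in the siDyrk2 library, which had 0 Y-linked fragments, so its level gives no share of male cells. A swap with a control library is argued against, since Dyrk2 in this library was 0.0865 of the lower control. The 7-base word GTAACAA scored -17.9 in siDyrk2 against siNeg and -0.73 in the knockout against wild type, which speaks against a swap of the knockout with siDyrk2 only if the word marks the siRNA, whose sequence is not known here. The embryos behind the knockout library thus may differ from those behind the other 3 in more than Dyrk2.

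A set of 63 protein-coding genes differed 2-fold with siRNA and less than 2-fold in the knockout, 26 lower and 37 higher, and no biological explanation was tested for it. The cut at 2-fold does not make the set particular to siRNA. Some members, such as F3, Meox1 and Mt2, came close to it in the knockout in the same direction, while others, such as Ssr1, did not. In 13 of the 63 genes siDyrk2 also differed at least 2-fold from both wild type and the knockout in the same direction. Off-target silencing through an siDyrk2 seed predicts a shared 7-base word in 3' untranslated regions. Among 10969 genes the word GTAACAA had a statistic of -17.9 in siDyrk2 against siNeg, beyond the lowest of 100 gene permutations (-5.09), and -0.73 in the knockout comparison. It was present in 14 of the 26 lower genes (53.8%), Ssr1 among them, and in 8.64% of all searched genes. The word was picked on the same ratios that define the lower genes, so this share is no separate evidence. By the statistic over all searched genes, seed-driven silencing may account for part of the lower genes. In siNeg against wild type the word TGACGTA had a statistic of -16.0, beyond the lowest of 100 permutations (-5.22). It was present in 7 of the 37 higher genes (18.9%), Kif1a among them, and in 2.03% of all searched genes. The siNeg library that served to pick this word also defines the higher genes, so this share is no separate evidence either. An siNeg seed may account for a smaller part.

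Departure of the siNeg library alone covered 17.5% of the 63 genes, those at least 2-fold different from wild type in the opposite direction, and the other genes stay open. After removal of a GC and length trend 87.3% were still 2-fold different, short of the 90% set beforehand for ruling a trend out, so a part played by such a trend cannot be told apart for the others.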

How the results depend on the processing

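Exchanged controls, genes without the 7-base words and pseudocounts in the joint fit were tests chosen after the results were seen. Trimmed-mean and median-of-ratios scaling used factors of 0.983 to 1.018, too near 1 to test directions. They moved 157 of 1198 values for named genes and lists past their interval. Counts by the rule of size depended on the treatment of low values. The counts for the knockout, siRNA and control comparisons were 504, 428 and 268 with a pseudocount of 0.25 FPKM, 22, 33 and 11 with 5 FPKM, and 56, 57 and 15 with a filter of 10 FPKM. A 1.5-fold rule gave 851 and 835 genes for knockout and siRNA, and protein-coding genes alone 112 and 86. The siRNA counts were 96 higher and 102 lower by the main rule, but 246 and 182 with a pseudocount of 0.25 FPKM. They were 484 and 351 with the 1.5-fold rule, so which direction held more genes depended on the setting. Genes in the same direction in both comparisons numbered 93, 8 and 11 with the low pseudocount, the high pseudocount and the filter, and the correlation across genes was 0.196, 0.277 and 0.321. The Hedgehog target median was -0.28 in the knockout and -0.17 with siDyrk2 with a pseudocount of 5 FPKM, and -0.22 and -0.09 with a filter of 10 FPKM. The core Hedgehog list of 4 genes had medians of -2.52 in the knockout and -2.28 with siDyrk2. With siNeg as the control for the knockout 428 genes differed and the G2/M median was -1.55. The joint fit with limma called 0 genes under each alternative that kept all 4 libraries, with 404 to 1300 at an unadjusted p under 0.05, and 0 to 2 genes when 1 library was left out, in fits without the approach term. The 2 genes, Gli1 and Ptch1, were called without the knockout library and again without the siDyrk2 library, each time lower. In these fits the lowered group was 1 library, so the spread came from the controls alone. The alternatives that kept all 4 libraries tested 4939 to 24334 genes, so their numbers under 0.05 cannot be read against 1 chance value. Without the approach term 597 of 12219 genes were under 0.05 by limma, against 611 by chance. Planned count-model alternatives were not run, because the values are FPKM, and scaling to total fragments is the deposited scaling itself. No paired analysis was possible because the groups share only replicate number 1, and the approach term of the joint fit blocks by method and not by embryo or culture.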

Other observations

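The test without genes that carry a 7-base word was chosen after the results were seen. The siRNA control had its own profile. Against wild type, the metallothionein gene Mt2 (-1.54), the chemokine gene Ccl2 (-1.24) and Sfrp2 (-0.88) were lower in the siNeg library, and Tgm2 (0.60) and Isg15 were higher, the latter at 12.67 against 7.02 FPKM. Mesothelial markers were higher in 4 of 4 genes with siNeg (median 0.38), in 4 of 4 in the knockout (0.46) and in 3 of 4 with siDyrk2 (0.36). The endothelial transcription factor gene Sox18 was at 0.03 FPKM in the knockout against 1.11, and at 0.06 with siDyrk2 against 2.07, with 1 and 2 fragments in the lowered libraries. The ratios were 37.0 (counting interval 6.69 to 1588) and 34.5 (9.59 to 303). The Wnt antagonist gene Dkk2 was at 15.15 against 27.92 FPKM in the knockout and 13.81 against 25.30 with siDyrk2, whereas Lgr5 was higher in both (0.70 and 0.95). Lgr5 was lower with siNeg than in wild type (-0.64), so the 0.95 rests in part on a low siNeg value.

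Other lists had these medians in the knockout and siRNA comparisons: -0.06 and 0.07 for p53 targets, 0.03 and 0.06 for heat shock genes, -0.03 and -0.01 for the ATF4 list, -0.02 and 0.01 for Wnt targets, 0.07 and 0.06 for Notch and BMP targets, and 0.05 and 0.08 for Hox genes. Replication-dependent histones had 0.13 and 0.03, and cilium disassembly factors -0.11 and 0.03, with 2 of 7 at least 2-fold lower in the knockout. In the knockout comparison, hypoxia genes had -0.01, ribosomal protein genes -0.00 and mitochondrially encoded genes -0.01. Cartilage markers had 0.13 and -0.03 and endothelial markers -0.09 and -0.53. Adipocyte markers had 0.16 with siDyrk2, sex-linked genes 1.78 in the knockout and 0.00 with siDyrk2, and the co-receptors 0.22 and -0.30. Lists with 1 or 2 measured members had -0.28 and 1.01 (skeletal muscle), -0.04 and -0.06 (bone), 0.48 and 0.33 (epithelial), -0.23 and 0.56 (neural) and 0.29 and 0.28 (hepatocyte). Of 9 erythroid markers 0 reached 1 FPKM. Adjusted over the list alone, the joint fit with limma had 5 of 19 interferon-stimulated genes higher, 4 of 14 NF-kB genes higher and 1 lower, and 3 of 3 mesothelial markers higher, against 0 over all genes. Of the 4 NF-kB genes, Ccl2 (28.40 against 28.76 FPKM) and Il1rl1 (2.17 against 3.84) were lower with siDyrk2 than in wild type. Ccl7 (35.18 against 16.91) and Nfkbia (10.88 against 10.02) were higher. Single genes adjusted over the list alone were Dkk2 and Sox18, lower, and Lgr5, Cd36 and Hspa1b, higher. Hspa1b was at 10.32 FPKM with siDyrk2, above siNeg (6.86) but below wild type (19.47). Xist, lower, and Krt19, higher, were each the only gene of their list in the fit, so their unadjusted p applied.

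The 7-base words bear on which siRNA differences are shared with the knockout. Ptch1, Hhip, Zim1, Serpinb9b, Prkacb, Ccne2 and Sparc carry GTAACAA in their 3' untranslated regions, and Gli1, Gli2 and Tgm2 carry neither word. Of 22 protein-coding genes lower in both comparisons 4 carry it (18.2%). When genes with either word were left out 28 genes remained at least 2-fold different in the same direction in both comparisons and 170 differed with siDyrk2. The Hedgehog target median was then -0.22, which says little about its strongly lower members. Gli1 (-3.26) and Gli2 (-1.12) were lower with siDyrk2 without either word. Other words also scored beyond the lowest permutation in siDyrk2 against siNeg, such as GTATCAA (-7.71) and GATTTTA (-7.37). They were not looked up in these genes or in those left after the removal. Only the longest coding transcript of each gene was searched. Absence of both words thus does not exclude a seed effect. Prkacb was at 15.77 FPKM in the knockout and 15.78 in wild type. Its lower level with siDyrk2 may in part be a seed effect, which was not tested for this gene. The statistic of -17.9 is over all 948 genes that carry GTAACAA, with an average log2 effect of -0.17. Prkacb was also lower with siNeg than in wild type (-0.52), although it does not carry the siNeg word.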
